A study of Arabidopsis thaliana with 8 samples.

How the data were processed

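Rosette leaves of Arabidopsis thaliana were profiled on Affymetrix ATH1 arrays, on which each transcript is read by a set of short oligonucleotides called a probe set. Per the labels' protocols, plants had 3 weeks of continuous light on soil, then 8 h of darkness, and were harvested after 2 h of renewed light. There were 4 lines with 2 arrays each: wild type of the Columbia background (WT), a T-DNA insertion mutant of FLU (flu), an overexpressor of the thylakoid-bound ascorbate peroxidase (tAPX, line 14/2) and flu plants carrying that overexpressor (flu tAPX). The experiment was done 6 times, each line being represented by no fewer than 10 plants each time, and each array received RNA pooled over 3 of them. A replicate is therefore a pool, and the spread between 2 arrays of a line is smaller than the spread between single harvests would be.

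Lines and replicate numbers were taken from the sample titles. The free-text sample descriptions differ from the titles and protocols at several points: they name the Landsberg accession, call flu samples wild type and tAPX samples flu, and give harvest after 60 min or 30 min for some arrays in place of 2 h. The titles, source names, genotype entries and the design text give the 4 lines and 2 h alike, and these were followed.

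The deposited values are MAS5 signals on a linear scale, per the submitters' processing notes, which name MAS5; its version is not given in the sources used here. MAS5 summarises each probe set from its perfect-match and mismatch oligonucleotides and multiplies each array by 1 factor. The middle 96% of the deposited signals averaged between 499.784 and 499.798 on every array, which fixes the scale of each array on its own mean. With this scaling, a large rise of many abundant transcripts lowers the signal of all others. The signals were not on a log scale and none was removed: 22810 probe sets, 64 of them controls, had a value on each array. The number of arrays limits the precision, since each line has 2.

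Values were turned into log2(signal + 16), with no further normalization. A log2 change on this scale understates the change of dim probe sets. Control probe sets were left out, and a probe set was kept when it lay above the 40th percentile of its own array on at least 2 of the 8 arrays, which left 14947. All 8 arrays entered 1 linear model of the 4 line means in limma 3.58.1 (R 4.3.3), with moderated variances that follow a trend on mean signal (4 residual degrees of freedom and a median of 5.94 prior degrees of freedom). P-values are two-sided, and those called adjusted went through the Benjamini-Hochberg procedure with a threshold of 0.05. The contrasts were flu against WT, tAPX against WT, flu tAPX against flu, flu tAPX against tAPX, the interaction (the difference between the last and the first of these responses to flu) and the mean of the 2 responses to flu. The mean response is statistically independent of the interaction in this balanced layout, so it was used to pick flu-responsive probe sets (adjusted p under 0.05 and a change of at least 2-fold) on which the interaction was then summarised. On simulated arrays built from the real means, with 200 of 14947 probe sets changed, the fit of flu against WT recovered 29.9% of 2-fold, 88.1% of 4-fold and 97.0% of 8-fold changes. For the interaction these shares were 7.46%, 70.1% and 87.9%. Far fewer probe sets changed there than in the real response to flu, and the threshold loosens as more change. The simulated lines were otherwise alike and the noise was independent between probe sets. These shares therefore describe that setting and not the real comparisons.

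Gene names came from a table of the platform's annotation, with symbols updated through NCBI gene identifiers to the TAIR10.1 annotation. Of all probe sets, 13513 had 1 gene, 503 had several and 8794 had none in that table, and of the tested ones 8124 had 1. No gene was named from a probe set with several. The genome build behind the array's design is not given in the sources used here, so no coordinates are printed. FLU itself has no probe set named in that table and is not analysed here. Gene lists were tested with camera in limma on 1 probe set per gene (the brightest), with a correlation between genes of 0.01 and again with an estimated correlation, adjusting within a comparison over the lists fixed beforehand and over the added families separately.

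The lists, the model, the filter, the pseudocount, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise. Of these lists 24 were built, 23 written from general knowledge and 1 of plastid-encoded genes. A planned list of mitochondria-encoded genes was not built. The 23 lists held 379 different genes in all, of which 49 were measured by a tested and named probe set. Of the 24 lists, 11 had at least 3 measured genes and were tested. For lists of the cell types a rosette could hold besides mesophyll, 2 guard-cell genes and no root, flower, phloem, trichome or meristem gene were measured, too few for a test. Counts of list members in the results refer to measured genes only. A further 24 families, taken by symbol, were added after the gene names on the array had been seen but before any expression values were compared, and 22 of them had at least 3 measured genes. The symbol pattern for defensin-like genes also took in 2 peptide deformylase genes, PDF1A and PDF1B, and the values without them were computed after the data had been seen.

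The genes named are the 10 highest and 10 lowest log2 changes among probe sets that passed the test, named 1 gene and had the arrays of the lines fully apart, the 4 members of each list with the largest change in either direction, and TAPX. Where fewer than 5 genes passed, the 5 highest and the 5 lowest moderated t values are also given, as not past the test. Only part of these are printed. The probe set with the steepest fall in flu was added outside this rule after its values were seen. The alternatives were a fixed or random replicate block, quantile normalization, median centring, pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, variances without a trend, only the 4 arrays of the lines compared, no probe sets shared between genes, a 2-fold minimum, each array left out in turn, and for the lists an estimated correlation and the mean of a gene's probe sets. Scaling on spike-in controls, the interaction tested on flu-responsive probe sets alone, and the count of probe sets at which a line stands apart without the pseudocount were added after the data had been seen.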

Results

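The series asked how extra thylakoid ascorbate peroxidase, an enzyme that removes hydrogen peroxide at the photosynthetic membrane, acts on gene expression in the flu mutant. FLU restrains the synthesis of chlorophyll precursors, and flu plants build up protochlorophyllide in the dark, which releases singlet oxygen when light returns. The data are 8 arrays of rosette leaves taken after 8 h of darkness and 2 h of light, with 2 arrays for each of WT, flu, tAPX and flu tAPX. Median signals lay between 153 and 166 on the 8 arrays. Replicate arrays of a line correlated across probe sets with r between 0.938 (flu tAPX) and 0.981 (tAPX). WT arrays correlated with tAPX arrays at 0.960 to 0.971, flu arrays with flu tAPX arrays at 0.935 to 0.972, and arrays with a functional FLU gene with flu arrays at 0.778 to 0.857. Probe sets are not independent replicates, so these values only describe the arrays.

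TAPX, the gene of the thylakoid ascorbate peroxidase, was measured first as a check of the labels. Its signal was 2836 ± 394 in WT and 22501 ± 648 in tAPX (mean ± SD, n = 2), a log2 change of 2.99 ± 0.15 (SE) with an adjusted p of 3.49e-05. In flu it was 1693 ± 51.3 and in flu tAPX 22963 ± 367, a log2 change of 3.75 ± 0.15 with an adjusted p of 3.8e-06. The endogenous gene was lower in flu than in WT (log2 -0.73 ± 0.15, adjusted p = 0.0062), while the 2 overexpressing lines differed by 0.03 ± 0.15 (adjusted p = 0.900). Without WT replicate 2 the difference of TAPX between flu and WT, then -0.59, no longer passed.

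The first comparison set flu against WT and asked how the mutant differs after 8 h of darkness and 2 h of light. No array was taken before the light returned. Differences already present in the dark therefore cannot be told apart from a response to the light. The genes raised in flu included some for small heat shock proteins, calcium-binding proteins, stress transcription factors and detoxifying enzymes. AT2G29500 and AT1G53540, which encode cytosolic small heat shock proteins, rose by log2 5.85 ± 0.39 and 5.95 ± 0.63, and AT5G51440, a mitochondrial small heat shock protein, went from a signal of 156 ± 25.8 in WT to 6860 ± 726 in flu (n = 2). AT1G53540 was the only measured member of the heat shock list, too few for a test of the list. In all, 3570 of 14947 probe sets passed, 1701 higher and 1869 lower in flu; 1349 of the higher and 574 of the lower ones changed at least 2-fold, and 269 against 4 changed at least 8-fold.

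All 3 measured members of the early singlet oxygen list were higher in flu. STZ, a zinc finger repressor of stress responses also known as ZAT10, had a signal of 165 ± 21.3 in WT and 5021 ± 343 in flu (log2 4.81 ± 0.18, adjusted p = 3.05e-07). AT5G64870, a flotillin-like gene, rose by log2 2.51 ± 0.24 and the AAA-ATPase gene AT3G28580 went from 60.5 ± 6.52 to 200.1 ± 4.73. Adjusted over the list alone, 3 of 3 passed as well, and camera placed the list above other genes (adjusted p = 0.000122). With an estimated correlation the adjusted p was 0.107. AT3G28580 no longer passed without WT replicate 2 (log2 1.41), flu replicate 1 (1.52) or flu replicate 2 (1.48).

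The calcium and touch list had 3 measured members, all raised: CML38 by log2 5.38 ± 0.33, CML37 by 4.80 ± 0.30 and AT1G76640 by 2.58 ± 0.58, all encoding calmodulin-like calcium-binding proteins (camera adjusted p = 0.000125). The WRKY list had WRKY6 (log2 3.65 ± 0.36), WRKY22 (1.93 ± 0.47) and WRKY53 (1.69 ± 0.25), again 3 of 3 higher (camera adjusted p = 0.000899). All 3 passed in each when adjusted over the list alone. For both lists the adjusted p with an estimated correlation was 0.107. Without WT replicate 2, flu replicate 1 or flu replicate 2, AT1G76640 (log2 2.12, 2.54 and 2.62) and WRKY22 (1.12, 2.02 and 1.85) did not pass. The wider WRKY family, added by symbol, had 3 of 5 members higher and was not set apart by camera (adjusted p = 0.0725). In the wider calmodulin-like family, which was added by symbol, 4 of 6 members were higher, CML42 by log2 2.57 ± 0.27 (camera adjusted p = 0.000119, or an adjusted p of 0.488 with an estimated correlation).

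Jasmonate genes were represented by 3 members, 2 of which rose. OPCL1, a coenzyme A ligase that feeds jasmonate precursors into peroxisomal oxidation, went from 764 ± 30.4 to 6106 ± 382 (n = 2), and JMT, which makes methyl jasmonate, rose by log2 1.46 ± 0.19. The defensin PDF1.2 had a log2 change of 0.81 ± 0.28 that did not pass over all probe sets (adjusted p = 0.0653), but passed without WT replicate 1 (1.27) or without flu tAPX replicate 1 (0.81). All 3 were higher when adjusted over the list alone. In the detoxification list 3 of 4 members rose: the glutathione transferases GSTU25 (log2 4.97 ± 0.52) and GSTU22 (2.23 ± 0.43) and the glycosyltransferase UGT73B5 (4.53 ± 0.21). GSTU20, the fourth, stood at 3675 ± 727 in WT and 3877 ± 1812 in flu (adjusted p = 0.989). The count adjusted over the list alone was again 3 higher. Camera gave an adjusted p of 0.000682 for each list, and with an estimated correlation the adjusted p was 0.107 for each. The wider family of glutathione transferases, added by symbol, had 2 of 11 members higher and 1 lower, with a camera adjusted p of 0.676.

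Tetrapyrrole synthesis was mixed. HEMA2, an isoform of glutamyl-tRNA reductase, the first committed enzyme, rose by log2 2.41 ± 0.29, whereas 5 of 9 members were lower and 3 did not pass. PORB, which converts protochlorophyllide in the light, had a signal of 5331 ± 98.7 in WT and 1782 ± 132 in flu (log2 -1.57 ± 0.19, adjusted p = 0.00023). HEME1 and HEME2, both uroporphyrinogen decarboxylases, changed by -1.08 ± 0.18 and -0.81 ± 0.15. Adjusted over the list alone, 1 was higher and 6 were lower, and camera did not set the list apart (adjusted p = 0.0768, or an adjusted p of 0.243 with an estimated correlation).

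Of 5 photosynthesis genes, LHCB4.2 (log2 -0.75 ± 0.15) and LHCB4.3 (-0.77 ± 0.22), which encode minor antenna proteins of photosystem II, were lower and 3 did not pass. The list held 34 genes, and its 5 measured ones as a set had a camera adjusted p of 0.261. Adjusted over the list alone the count was again 2 lower. LHCB4.2 did not pass without WT replicate 2 (log2 -0.66) or flu replicate 1 (-0.63) or with poly-A scaling (-0.70). LHCB4.3 did not pass without either WT array (-0.88 and -0.66), either flu array (-0.69 and -0.84) or either tAPX array (-0.77), with variances that follow no trend (-0.77) or with poly-A scaling (-0.72). In reactive oxygen scavenging, 1 of 5 genes was lower, AT3G52960, a chloroplast peroxiredoxin (log2 -0.92 ± 0.16), and SAPX, the stromal ascorbate peroxidase, had a log2 value of -0.32 ± 0.18 (adjusted p = 0.222). The count was the same 1 adjusted over the list alone, and the camera adjusted p was 0.261.

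None of 3 cold, drought and abscisic acid genes passed (camera adjusted p = 0.809), among them COR15A at log2 -0.22 ± 0.33 and COR47 at -0.18 ± 0.18. Of 3 auxin and growth genes, the auxin-conjugating enzyme GH3.3 was higher (2.08 ± 0.45) and the expansin EXPA8 lower (-1.66 ± 0.19), with a camera adjusted p of 0.675. GH3.3 did not pass without WT replicate 1 (1.96) or flu replicate 2 (1.97). None of the cold genes passed adjusted over the list alone, and of the growth genes 1 was higher and 1 lower. Of 68 plastid-encoded genes, limma called none, either over all probe sets or adjusted over the list alone. Their median log2 change was -0.04 while camera's direction for them was up (adjusted p = 0.588), and with poly-A scaling the median was 0.00.

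Among the families added by symbol, 14 of 33 UDP-glycosyltransferases were higher and 4 lower, UGT73B4 (log2 5.01 ± 0.26) being among the higher ones. UGT76E12 rose by 3.56 ± 0.41. Of 8 U-box ubiquitin ligases, 5 rose, including PUB19 (log2 3.72 ± 0.28), PUB23 (2.65 ± 0.27) and PUB24 (2.46 ± 0.20), the last 2 known as brakes on immune signalling. Serine carboxypeptidase-like genes had 4 of 14 lower and none higher (10 lower adjusted over the family alone), scpl26 by log2 -1.10 ± 0.19. Genes for assembly of thylakoid complexes had 4 of 11 lower (5 adjusted over the family alone), among them LPA66 (-1.08 ± 0.28), known for editing a photosystem II transcript, and CRR41, with a signal of 451 ± 32.9 in WT and 219.5 ± 44.8 in flu. Camera adjusted p-values were 0.000142, 0.000525, 0.0116 and 0.0311 for these 4 families in turn, and with an estimated correlation the adjusted p-values were 0.312, 0.312, 0.544 and 0.544. The carboxypeptidase call was lost without WT replicate 2 (adjusted p = 0.0523) or with no filter (0.171), and the assembly call without WT replicate 1 (0.103) or flu replicate 2 (0.112) or with a filter at the 60th percentile (0.0652). LPA66 did not pass when either WT array (-1.19 and -0.96) or either flu array (-1.14 and -1.01) was left out, nor CRR41 without WT replicate 1 (-0.93) or flu replicate 2 (-0.80).

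Other large changes were those of CCR2, a cinnamoyl-CoA reductase of lignin synthesis (log2 5.67 ± 0.35), the receptor-like kinase B120 (5.45 ± 0.50) and AT3G02840 (5.53 ± 0.29). AT2G04400, an enzyme of tryptophan synthesis, rose by 1.51 ± 0.17, and LYC, the lycopene beta-cyclase of carotenoid synthesis, fell by 0.79 on the log2 scale (SE 0.17), a call lost without WT replicate 2 (-0.68) or flu replicate 1 (-0.71) or with poly-A scaling (-0.74). With the pseudocount of 16, the steepest fall of all tested probe sets was that of 1 which has no gene in the table used here and was singled out after its values were seen. Its signals were 1254 to 1307 on the WT and tAPX arrays, 7.91 and 8.56 in flu and 33.6 and 60.5 in flu tAPX (log2 -5.75 ± 0.26 in flu against WT, adjusted p = 5.22e-07). The flu signals are so dim that the size of this fall depends on the pseudocount as well, between -7.13 and -4.23 over the other settings. Named genes lower in flu included AT1G13650 (log2 -2.38 ± 0.20) and AT3G15570 (-2.27 ± 0.22). AT5G24240 (-3.64 ± 0.57) and AT3G17640 (-3.14 ± 0.50) were lower as well, again with dim signals in flu (6.15 to 24.9).

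The median log2 change of all tested probe sets was -0.20, so changes near that value do not differ from the middle of the array. Without WT replicate 1 or 2, 1962 or 1852 probe sets passed, without flu replicate 1 or 2, 2275 or 2285, and with each array scaled on its poly-A spike-in controls, 2335, of which 65.7% were higher in flu against 47.6% as deposited.

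**Figure D1:**
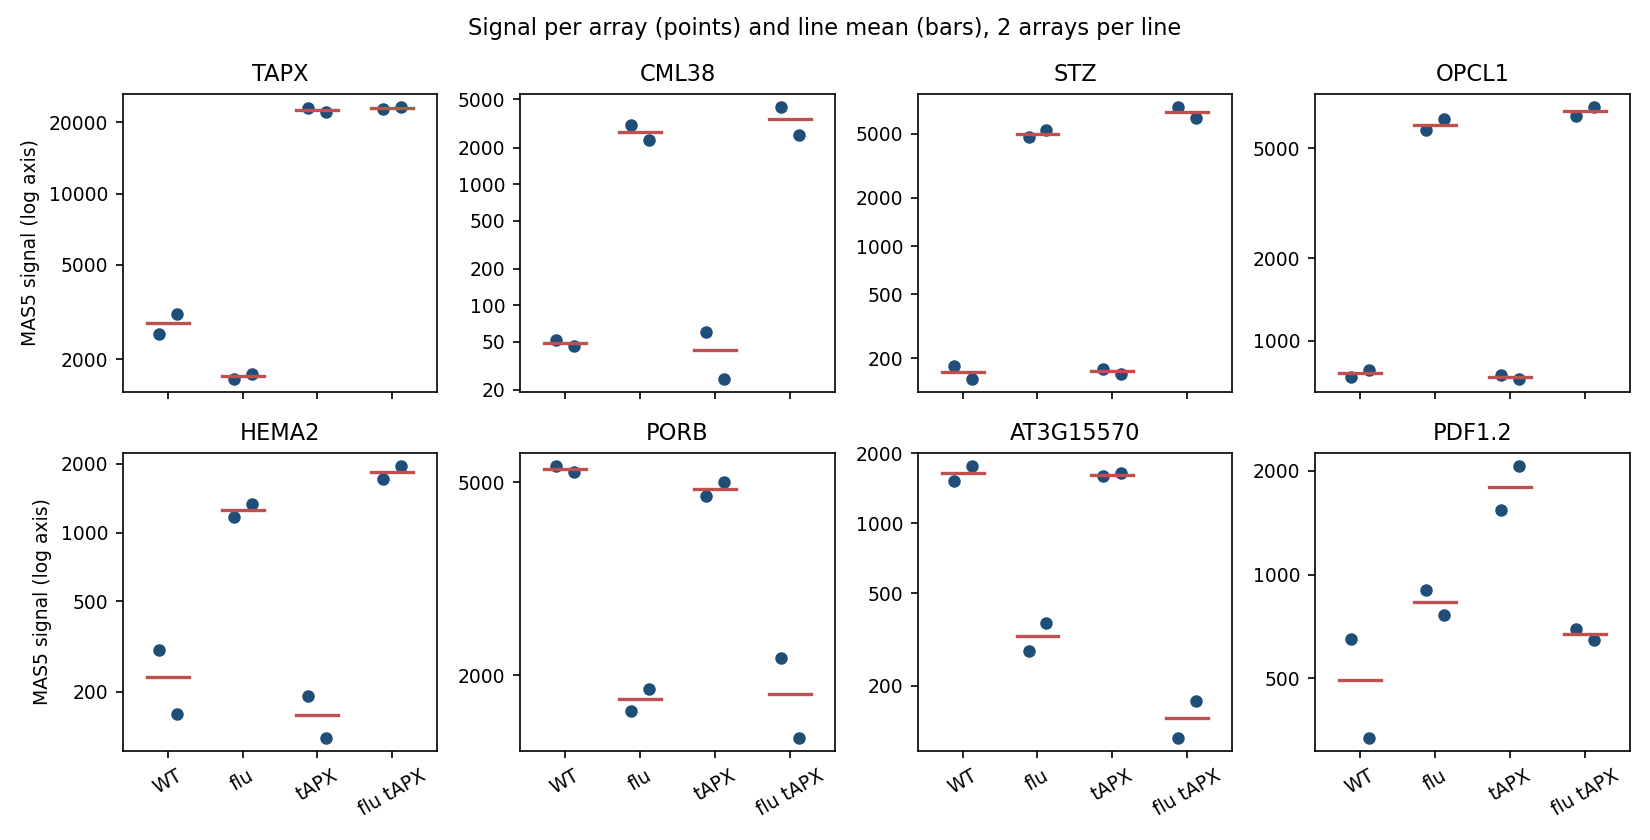
MAS5 signal on a log axis for 8 genes, each panel showing the 2 arrays of every line as points and the line mean as a bar. TAPX separates the overexpressing lines (22043 and above) from the others (3115 and below), CML38, STZ, OPCL1 and HEMA2 are high and PORB and AT3G15570 low in both flu lines, and PDF1.2 is highest in tAPX (mean 1801).

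The second comparison set tAPX against WT and asked what the transgene does in plants with a functional FLU gene. TAPX was the only probe set that passed. limma called no other gene: 578 probe sets had an unadjusted p under 0.05, against 747 expected by chance. Among the named genes with the highest and lowest moderated t values, none of them past the test, were the defensins PDF1.2, with a signal of 493 ± 223 in WT and 1801 ± 373 in tAPX (log2 1.89 ± 0.28, adjusted p = 0.314), and PDF1.2b (2.56 ± 0.43, adjusted p = 0.471). On the low side were AT5G24240, with 337 ± 127 in WT and 9.55 ± 1.74 in tAPX (log2 -3.74 ± 0.57, adjusted p = 0.314), and UGT76E12 (-2.11 ± 0.41, adjusted p = 0.897). The starch-degrading enzyme AMY1 had a value of -1.01 ± 0.23 and the PHD-finger gene OBE1 of -1.17 ± 0.26, each with an adjusted p of 0.980.

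No list fixed beforehand was set apart by camera in tAPX against WT, the lowest adjusted p being 0.179 (jasmonate). No member of the 11 fixed lists passed over all probe sets, and adjusted over the list alone 1 did, PDF1.2 of the jasmonate list, which was higher. Of the added families, 4 defensin-like genes lay above other genes (median log2 1.49, camera adjusted p = 1.41e-05) and so did 8 autophagy genes (median 0.26, adjusted p = 0.0177), although no member of either passed singly. With an estimated correlation the adjusted p was 0.870 for each. The defensin-like call was lost with no filter (adjusted p = 0.203). As first taken by symbol that family also held the peptide deformylase genes PDF1A and PDF1B, and with them its adjusted p was 2.37e-05. Over the family alone, 2 defensins were higher; the probe set of PDF1.2b is of the kind that can also read related genes. ATG8E, which encodes a protein of the autophagosome membrane, had a signal of 286 ± 63.3 in WT and 523 ± 17.8 in tAPX (n = 2). SAPX differed by log2 -0.19 ± 0.18 (adjusted p = 0.980). The autophagy call was lost without WT replicate 1 (adjusted p = 0.0789), WT replicate 2 (0.147) or tAPX replicate 2 (0.1002), or with a filter at the 60th percentile (0.0925). Poly-A scaling moved the median log2 change of all tested probe sets from -0.06 to 0.11 and called 3 probe sets, TAPX and the defensins PDF1.2 (2.06) and PDF1.2b (2.73).

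The third comparison set flu tAPX against flu and asked whether expression differs with the extra peroxidase in flu plants after 2 h of light. TAPX was again the only probe set that passed, while 826 had an unadjusted p under 0.05, against 747 expected by chance. The genes below had large moderated t values or belonged to the lists, and none passed. AT3G15570 had a signal of 329 ± 64.4 in flu and 146 ± 37.2 in flu tAPX (log2 -1.09 ± 0.22, adjusted p = 0.870), AT4G12830 had 406 ± 2.02 and 207 ± 14.2 (-0.92 ± 0.20, adjusted p = 0.870), and the chloroplast thioredoxin ty2 had 2056 ± 148 and 1175 ± 162 (-0.80 ± 0.17, adjusted p = 0.870). AT5G07030, an aspartyl protease, stood at -1.69 ± 0.31 and SNF7.1, a protein of endosomal sorting, at 1.13 ± 0.22. Among raised genes, STZ differed by 0.44 ± 0.18, AT5G64870 by 0.39 ± 0.24, UGT73B5 by 0.65 ± 0.21 and CML38 by 0.31 ± 0.33, with adjusted p-values of 0.870, 0.879, 0.870 and 0.911. The antenna gene LHCB4.3 differed by -0.77 ± 0.22 (adjusted p = 0.870). SNF7.1 passed without flu tAPX replicate 1 (1.34).

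No list was set apart by camera in this comparison, the lowest adjusted p being 0.108 among lists fixed beforehand (singlet oxygen, photosynthesis) and 0.0876 among added families (beta-glucosidases, thylakoid assembly). No member of a fixed list passed over all probe sets, and adjusted over the list alone 1 photosynthesis gene was lower and 1 detoxification gene higher. Without flu tAPX replicate 1 more probe sets passed, but that fit rests on a single flu tAPX array and takes its spread from the other lines. It does not show that replicate 1 hid differences. With poly-A scaling, which moved the median log2 change of all tested probe sets from 0.00 to -0.51, 16 passed, 6.25% of them higher. AT5G07030 (-2.05), AT3G15570 (-1.58), AT4G12830 (-1.43) and ty2 (-1.34) were among the 16, and STZ, AT5G64870 and CML38 turned to -0.11, -0.14 and -0.23.

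The fourth comparison set flu tAPX against tAPX, the same response to flu in plants with extra peroxidase. Most of the probe sets raised or lowered in flu against WT changed the same way here, and many others were called as well. UGT76E12 rose from a signal of 18.3 ± 19.6 to 2103 ± 603 (n = 2, log2 6.05 ± 0.41), AT5G51440 by log2 6.24 ± 0.18, CML38 by 5.90 ± 0.33, and AT4G39670, of the glycolipid transfer protein family, from 125 ± 34.4 to 8753 ± 777. AT3G15570 and AT1G23205, of the pectin methylesterase inhibitor family, each fell by 3.35 on the log2 scale (SE 0.22 and 0.27). In all, 5014 probe sets passed, 2243 higher and 2771 lower, with 1720 and 1344 of them changed at least 2-fold. Of the probe sets called in flu against WT, 1596 (93.8%) of the higher ones were also higher here and 1372 (73.4%) of the lower ones also lower, where independent lists would share 255 and 346. Those shared sets made up 71.2% of the higher and 49.5% of the lower calls of this comparison; 1 probe set was called in opposite directions. The log2 changes of these 2 comparisons share no arrays and correlated across probe sets with r = 0.857 (Spearman 0.713). Their tests do share 1 estimate of the spread of each probe set. The values of 255 and 346 are therefore not an exact reference for the overlap.

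All 3 early singlet oxygen genes rose (STZ by log2 5.23 ± 0.18, AT5G64870 by 3.38 ± 0.24, AT3G28580 by 2.45 ± 0.34), as did all 3 of the calcium and touch list, CML37 among them (5.45 ± 0.30), and all 3 of the WRKY list, with WRKY6 at 4.36 ± 0.36 and WRKY53 at 2.53 ± 0.25. In the detoxification list 3 of 4 rose, with GSTU25 at 5.68 ± 0.52 and UGT73B5 at 5.16 ± 0.21. The counts adjusted over the list alone were the same for these 4 lists. Camera gave adjusted p-values of 0.000232, 0.000325, 0.00332 and 0.00624 for the 4 lists in turn. With an estimated correlation the adjusted p-values were 0.139, 0.201, 0.201 and 0.212.

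Jasmonate genes parted here: OPCL1 (log2 3.17 ± 0.15) and JMT (1.71 ± 0.19) rose and PDF1.2 fell, from 1801 ± 373 in tAPX to 670 ± 33.7 in flu tAPX (adjusted p = 0.0041), with a camera adjusted p of 0.0779. In the tetrapyrrole list 7 of 9 genes were lower, PORB by log2 -1.43 ± 0.19, HEME1 by -1.25 ± 0.18 and HEME2 by -1.09 ± 0.15, and HEMA2 was higher by 3.43 ± 0.29. Camera placed that list below other genes with an adjusted p of 0.0426 (adjusted p = 0.212 with an estimated correlation, 0.166 with poly-A scaling, 0.0662 with quantile normalization and 0.0989 with a filter at the 60th percentile). That call was lost when any array but flu tAPX replicate 2 was left out: adjusted p was 0.0559 without either WT array, 0.0511 without either flu array, 0.0617 and 0.0523 without tAPX replicates 1 and 2, and 0.0881 without flu tAPX replicate 1. PDF1.2 did not pass without tAPX replicate 2 (-1.18). Of the photosynthesis list, 4 of 5 were lower, LHCB4.3 by -1.73 ± 0.22 and LHCB4.2 by -0.94 ± 0.15 (camera adjusted p = 0.0569). In scavenging 2 of 5 were lower, AT3G52960 by -1.06 ± 0.16 (camera adjusted p = 0.274). The counts adjusted over the list alone were 2 higher and 1 lower for jasmonate, 1 higher and 8 lower for tetrapyrroles, 4 lower for photosynthesis and 3 lower for scavenging. Of the plastid-encoded genes 5 of 68 were lower, and none when adjusted over the list alone (camera adjusted p = 0.625). None of the 3 cold genes passed, and of the growth genes 1 was higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.799 for each).

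Among added families, 13 of 33 UDP-glycosyltransferases rose and 4 fell, with a median of 0.37 that turned to -0.30 with poly-A scaling, and 5 of 8 U-box ligases rose, PUB23 by 3.79 ± 0.27. Thylakoid assembly genes had 7 of 11 lower (8 adjusted over the family alone): CRR42 by log2 -3.26 ± 0.53, CRR21 by -1.84 ± 0.21, LPA19 by -1.61 ± 0.27 and LPA2 by -1.45 ± 0.19, genes known for assembly of the NDH complex or of photosystem II and, for CRR21, for editing of a plastid transcript. Camera adjusted p-values were 0.00311, 0.00163 and 0.00311 for these 3 families in turn, and the adjusted p with an estimated correlation was 0.350 for each. Of 4 defensin-like genes 3 were lower (4 adjusted over the family alone), PDF1.2b by -1.54 ± 0.43 and LCR68 by -1.83 ± 0.52 among them, and camera did not set the family apart (adjusted p = 0.103), although it did with the deformylase genes PDF1A and PDF1B included (0.0217). The call with them was lost with an estimated correlation (adjusted p = 0.362), with no filter (0.331), without flu tAPX replicate 2 (0.0865) and with poly-A scaling (0.0774). PDF1.2b did not pass without tAPX replicate 2 (-1.16) or flu tAPX replicate 2 (-0.96), nor LCR68 without either tAPX array (-1.99 and -1.66) or flu tAPX replicate 2 (-1.21), and neither passed with variances that follow no trend. SAG101, a partner of the immune regulator EDS1, rose by log2 1.52 ± 0.28 (adjusted p = 0.00262).

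Without tAPX replicate 1 or 2, 2942 or 2825 probe sets passed. With poly-A scaling 8850 passed, 14.3% of them higher against 44.7% as deposited, and the median log2 change of all tested probe sets moved from -0.16 to -0.79.

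**Figure D2:**
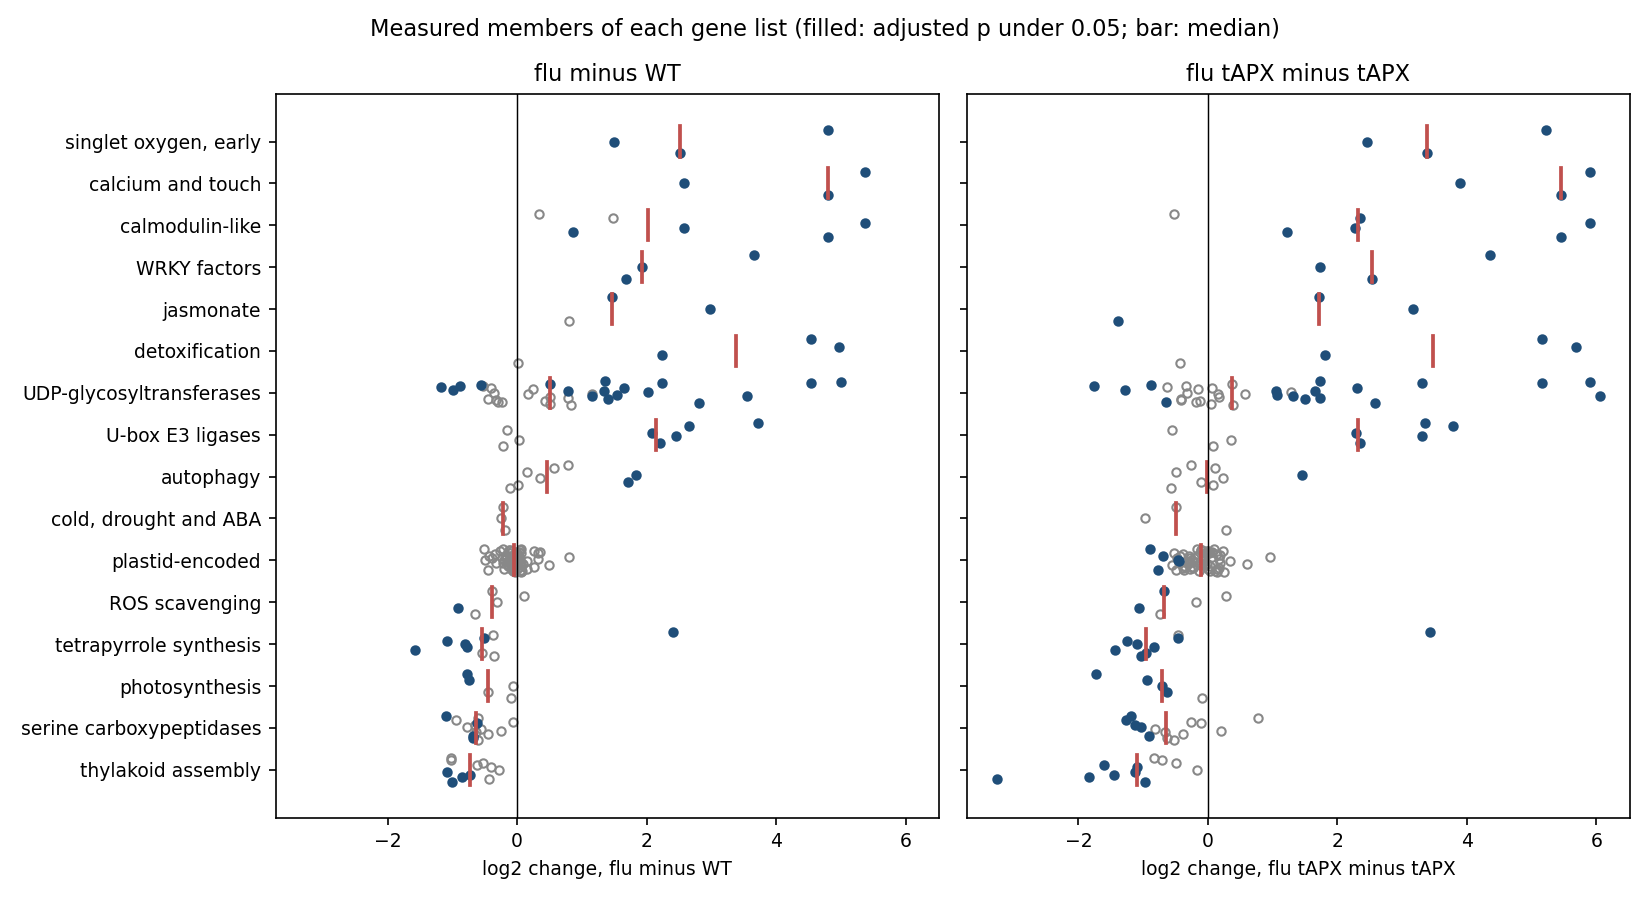
Log2 change of each measured member of 16 gene lists in flu minus WT (left) and flu tAPX minus tAPX (right), with filled points for members past an adjusted p of 0.05, open points for the others and a bar at the list median. The calcium and touch list has medians of 4.80 and 5.45 in the 2 panels, and the tetrapyrrole list has medians of -0.54 and -0.95 with HEMA2 alone above 0.

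The last comparison asked whether the response to flu differs between plants with and without extra peroxidase. The median response of the flu-responsive genes was larger in size with the transgene in the deposited values, and no single gene was called. Among 1626 probe sets raised in the mean of the 2 responses, 1259 (77.4%) had a larger rise in the tAPX background, with a median excess of log2 0.34; among 901 lowered ones, 665 (73.8%) had a larger fall, with a median excess of 0.32. Median responses were 1.74 without and 2.04 with the transgene for the raised set, and -1.10 and -1.42 for the lowered set. A line through 0 along the main axis of the 2 responses, that with the transgene against that without it, had a slope of 1.16. The slope was 1.13 to 1.26 when each array was left out in turn. It is not a regression slope, and a larger spread in 1 of the 2 responses can tilt it. By exact enumeration, the sum of the 2 medians (0.660) was the farthest from 0 of the 18 ways to deal the arrays to the lines with the response to flu held fixed, and the next had 0.629. With 18 ways no share under 0.05 can be reached. With poly-A scaling, which moved the median interaction of all tested probe sets from 0.06 to -0.62, the raised set reversed to -0.33 and the lowered set moved to 0.90. In the fits with 1 array left out, the sets were picked anew. Those layouts are unbalanced, so the mean response used for picking is no longer independent of the interaction. Picking then favours a larger excess without a flu tAPX array and a smaller one without a flu array. The lowered set picked without flu tAPX replicate 1 had a median of 0.68, and that picked without flu replicate 2 had 0.21.

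**Figure D3:**
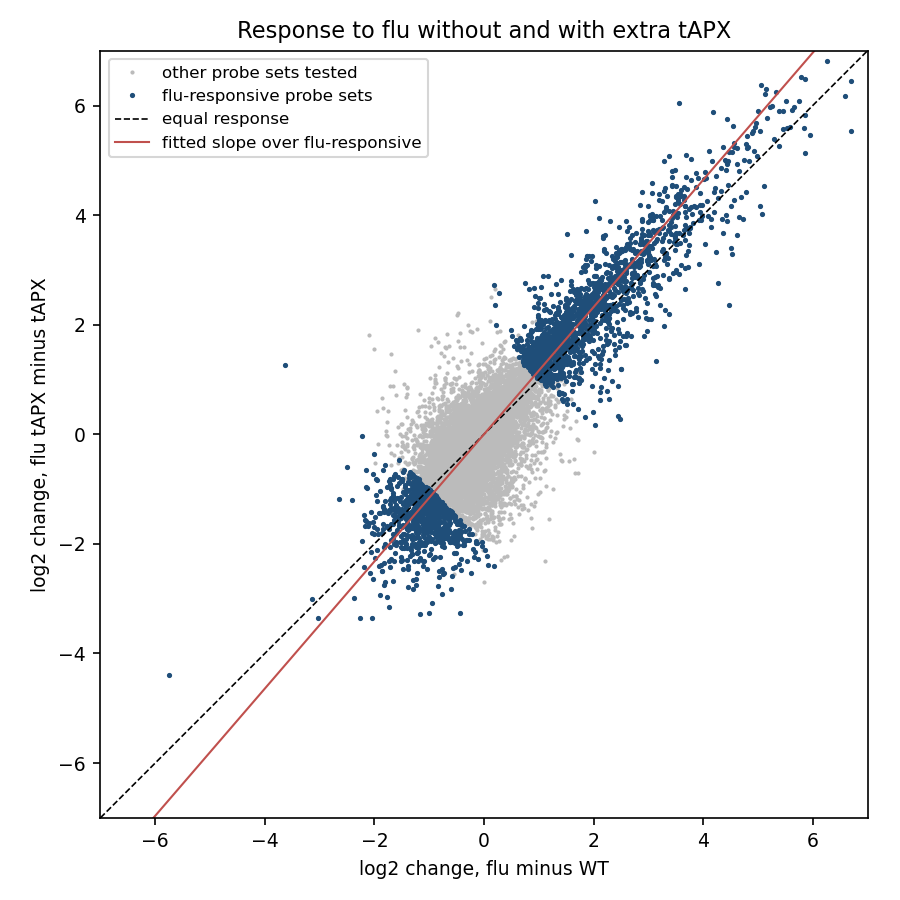
Log2 change in flu minus WT (x axis) against flu tAPX minus tAPX (y axis) for every tested probe set, with the flu-responsive ones in dark blue, the line of equal response dashed and the fitted slope of 1.16 in red. In these deposited values the fitted line is steeper than that of equal response. With poly-A scaling the median excess is -0.33 for the raised set and 0.90 for the lowered set.

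limma called no probe set for the interaction (lowest adjusted p 0.719), while 1031 had an unadjusted p under 0.05 against 747 expected by chance, and none passed when only flu-responsive probe sets were tested. The genes below had moderated t values among the highest or lowest, all short of the threshold at an adjusted p of 0.719. AT5G24240 (4.90 ± 0.80), AT3G21000 (3.90 ± 0.88), UGT76E12 (2.49 ± 0.58), AT5G66650 (1.53 ± 0.30) and AT2G38240, a jasmonate-related oxygenase gene (1.32 ± 0.28), had higher interaction values. AT3G02190 (-2.42 ± 0.44), PDF1.2 (-2.20 ± 0.40), AT2G21580 (-1.91 ± 0.40), AT1G76960 (-1.63 ± 0.35) and AT2G26240 (-1.54 ± 0.33) had lower ones. A fit without flu tAPX replicate 1 leaves that line 1 array and takes its spread from the other lines. Its interaction was 5.20 for AT5G24240, -2.59 for AT3G02190, -2.28 for AT2G21580, -2.25 for PDF1.2 and -1.79 for AT2G26240. With poly-A scaling, which moved the median interaction of all tested probe sets to -0.62, 514 passed and 0.195% of them were higher. Among the 514 were the same 5 genes and AT1G76960 (-2.31).

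Camera set 1 fixed list apart for the interaction, the early singlet oxygen genes (median 0.87, adjusted p = 0.0454), with AT3G28580 at 0.95 ± 0.49, AT5G64870 at 0.87 ± 0.34 and STZ at 0.42 ± 0.25, the last of which turned to -0.28 with poly-A scaling. With an estimated correlation the adjusted p was 0.486, and the call was lost in 10 of 19 other settings. The adjusted p was 0.0587 with quantile normalization, 0.0560 with a pseudocount of 64 and 0.0707 with no filter. Adjusted p was 0.280 and 0.0515 without WT replicates 1 and 2, 0.0867 and 0.0634 without flu replicates 1 and 2, 0.0572 without tAPX replicate 1 and 0.237 without flu tAPX replicate 1. No member of a fixed list passed over all probe sets, and adjusted over the list alone 1 jasmonate gene was lower.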

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

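Of the tests given here, the 2 on harvest times, the poly-A scaling and the defensin-like family without PDF1A and PDF1B were chosen only after the result was seen, while the tests of 1 array, of 1 scaling factor and of the 18 assignments were set out earlier.

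Outside the comparisons, 1 control probe set of the array, left out of every test, had signals of 4514 and 5269.5 in tAPX and 6069 and 7712 in flu tAPX, against 10.5 to 49.7 on the 4 arrays without the transgene. Its target is not named in the tables used here, and no biological explanation was tested.

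Several gene groups stood apart in the interaction, the difference between the 2 responses to flu. Camera gave an adjusted p of 0.0454 for the early singlet oxygen genes, 0.000137 for the defensin-like family as taken by symbol (median log2 -1.42), 0.0314 for the autophagy genes (median -0.46) and 0.0314 for the thylakoid assembly genes. The assembly genes had a median of -0.05 and a mean of -0.51, so their lower mean came from part of the list, CRR42 among them at -2.83, which passed the test only with poly-A scaling (-3.38). Adjusted over the family alone, 2 assembly genes were lower. With an estimated correlation the adjusted p-values were 0.486 for the singlet oxygen genes and 0.660 for the other 3 groups. Arrays left out singly ended the autophagy call without WT replicate 2 (adjusted p = 0.0676), flu replicate 1 (0.221), tAPX replicate 2 (0.0612) or flu tAPX replicate 2 (0.272). The assembly call ended without WT replicate 2 (0.0676), flu replicate 1 (0.221), tAPX replicate 2 (0.0633) or flu tAPX replicate 1 (0.387). Poly-A scaling ended the assembly call (0.237) and a filter at the 60th percentile the autophagy call (0.157). The defensin-like family by symbol held 2 peptide deformylase genes, PDF1A and PDF1B, and without them its 4 other genes had a median of -1.87 and an adjusted p of 0.000779 (0.660 with an estimated correlation), 2 of them lower adjusted over the family alone. That call was lost with no filter (0.133) and in no fit with 1 array left out.

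For 9 named genes short of the threshold, extra tAPX went with opposite differences in plants with and without a functional FLU gene, on every array. These 9 were taken from genes with moderated t values for the interaction among the highest or lowest. Opposite differences are in part a product of that choice. That contrast of directions was not tested apart from the interaction, which none of the 9 genes passed. Both tAPX arrays lay below both WT arrays, and both flu tAPX arrays above both flu arrays, for AT5G24240, AT3G21000, AT5G66650 and AT2G38240, with log2 interactions of 4.90, 3.90, 1.53 and 1.32. The order was the reverse for the other 5 of these 9 genes, with an interaction of -2.42 for AT3G02190, -2.20 for PDF1.2, -1.91 for AT2G21580, -1.63 for AT1G76960 and -1.54 for AT2G26240. Further named genes showed 1 or the other order too, AT5G64870 the first and LHCB4.3 the second. How many of all tested probe sets do so was not counted. The 2 largest interactions among the 9 genes rest on dim signals. AT5G24240 had 7.32 to 59.8 on the flu, tAPX and flu tAPX arrays, where the 40th percentile of an array was 78.4 to 95.6. AT3G21000 had 6.87 to 34.1 on the flu and tAPX arrays. Its interaction lay between 2.08 and 5.89 over the settings other than arrays left out and poly-A scaling.

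The larger median response to flu with the transgene was weighed against technical explanations. Leaving out flu tAPX replicate 2 left the raised set's median at 0.336. That set was picked anew without this array, in an unbalanced layout where picking favours a larger excess. The value therefore does not exclude this array as the cause. With all arrays the lower of the raised and lowered medians was 0.322, where 1 scaling factor per array would move these 2 medians in opposite directions. The sample descriptions give flu and flu tAPX the same harvest time within a replicate number. If those times were the whole cause, no excess would remain within a replicate number. If the times given for WT and tAPX were, none would remain between flu tAPX and flu. The lower medians there were 0.277 and 0.245. The descriptions conflict with the titles, so these values bear only on times as written there, not on real harvest times. Chance stays open: 1 of 18 assignments of the arrays had a sum of medians as far from 0 (0.660, the next 0.629), too few ways for a share under 0.05. An action of the transgene may also account for it and was not tested apart from chance, and under poly-A scaling the raised set alone reverses, to -0.33.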

How the results depend on the processing

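Among the tests below, poly-A scaling, the interaction on flu-responsive probe sets alone and the defensin-like family without 2 deformylase genes were chosen only after the result was seen. Over 155 pairs of a named gene and a comparison, 2967 of 3060 alternative fits kept direction and side of the threshold, 48 fell short of it (17 pairs at least once), 29 newly passed it and 16 reversed. No pair with a reversed fit had passed the test in that comparison, although some of these genes passed in others. Outside these pairs, called probe sets did reverse with poly-A scaling, as given below.

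Poly-A scaling gave 2335 calls in flu against WT, 3 in tAPX against WT, 16 in flu tAPX against flu, 8850 in flu tAPX against tAPX and 514 for the interaction. Of the 8850, 4039 were also called without it and 118 of these had the opposite sign. Under it the raised set's median interaction reversed to -0.33, the lowered set's was 0.90, and these values reversed: TAPX in flu tAPX against tAPX (-0.64), STZ (-0.11), AT5G64870 (-0.14) and CML38 (-0.23) in flu tAPX against flu, STZ in the interaction (-0.28) and FMA in flu against WT (0.0108). A 2-fold minimum left 1923, 3064 and 2527 calls in flu against WT, flu tAPX against tAPX and the mean response, by construction. The lowered set's median was 0.38 with median centring, 0.29 with no filter and 0.36 with a filter at the 60th percentile. Of 11 camera calls for fixed lists, 5 were left at the 60th percentile, where the singlet oxygen and calcium lists have under 3 genes and give no value, and 0 with an estimated correlation. Quantile normalization turned GSTU20 (-0.028) and FMA (0.011) in flu against WT, and median centring FMA (0.0071). Apart from the 2-fold minimum and the loss of genes at the 60th percentile, the cause was not tested.

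With 1 array left out, a line with 1 array was assumed to vary like the others. The raised and lowered sets were picked anew each time, in layouts where picking is not independent of the interaction. The calls then ranged from 1852 to 4663 in flu against WT, from 1 to 72 in flu tAPX against flu, from 2825 to 5364 in flu tAPX against tAPX, from 0 to 185 for the interaction and from 4885 to 7039 for the mean response, and there was 1 in tAPX against WT each time. The raised median ranged from 0.27 to 0.41, the lowered from 0.21 to 0.68 and the list calls from 9 to 16. TAPX ranged from 2.85 to 3.13 in tAPX against WT and from 3.72 to 3.78 in flu tAPX against flu. Signs turned within the ranges of GSTU20 (-0.49 to 0.50), COR47 (-0.40 to 0.034), FMA (-0.12 to 0.055) and AT1G22690 (-0.25 to 0.44) in flu against WT and CML38 (-0.068 to 0.69) in flu tAPX against flu.

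Replicate numbers are shared by the 4 lines, but the labels do not say that they pair samples, and deviations of same-numbered arrays correlated between -0.08 and 0.35. With a fixed replicate block 3963, 2, 1, 5521 and 0 probe sets passed in the 5 comparisons in turn, UGT76E12 being the added call in tAPX against WT and PDF1.2 (0.81) passing in flu against WT, and with a random block 3812, 1, 1, 5252 and 0. The fixed block also ended 2 camera calls for the interaction, of the singlet oxygen genes (adjusted p = 0.0780) and of the assembly genes (0.0504). Without the deformylase genes the defensin-like family lost its call in flu tAPX against tAPX (0.103). Signal over background is known only through the filter, since detection calls were not used here, and dim genes such as AT5G24240 have folds that move with the pseudocount, its interaction lying between 2.95 and 6.89 over the settings other than arrays left out and poly-A scaling.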

Other observations

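Of the tests given here, the other splits of the arrays, the spike-in test and the search for probe sets at which WT stands apart were chosen only after the result was seen.

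Cell wall and membrane genes outside the groups above parted in flu against WT. Of 5 xyloglucan endotransglucosylases, enzymes that remodel cell wall polymers, 2 were higher and 1 lower (2 and 2 adjusted over the family alone): XTH18 rose by log2 4.55 ± 0.47 and XTH32 went from a signal of 2814 ± 6.30 in WT to 909.7 ± 38.3 in flu (n = 2). The median of the family was -0.76, its mean 0.51 and its camera direction up, with an adjusted p of 0.967. In flu tAPX against tAPX 2 were higher and 3 lower, with XTH18 at 5.63 ± 0.47. Of 7 tetraspanins, membrane proteins with 4 spans, 2 rose and 1 fell in flu against WT (2 higher and 4 lower adjusted over the family alone), with a median of -0.48, a mean of 0.47 and a camera adjusted p of 0.820. TET8 went from 1986 ± 149.8 to 10152 ± 1317, and TET9 rose by log2 2.95 ± 0.46. Among single genes, AT1G05575 rose by 5.87 ± 0.60 and AT4G01460 fell by 2.23 on the log2 scale (SE 0.32).

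Autophagy genes had 2 of 8 members higher in flu than in WT (3 adjusted over the family alone), ATG8H by log2 1.84 ± 0.35 and ATG8G by 1.72 ± 0.49, both coding for proteins of the autophagosome membrane. Camera placed the family above other genes (adjusted p = 0.0311, or an adjusted p of 0.628 with an estimated correlation). That call was lost without WT replicate 1 (0.0512), WT replicate 2 (0.0619) or flu replicate 1 (0.137), and with a filter at the 60th percentile (0.139). ATG8H did not pass without WT replicate 2 (1.54), nor ATG8G without WT replicate 1 (1.29), either flu array (1.65 and 1.78) or either tAPX array (1.72). In flu tAPX against tAPX, ATG8H rose by 1.45 ± 0.35, a call lost without tAPX replicate 1 (1.33), and the other 7 did not pass. The guard-cell genes FMA and AT1G22690 had log2 values of -0.03 ± 0.24 (0.01 with poly-A scaling) and 0.10 ± 0.49 in flu against WT, and neither passed in any comparison. AT1G22690 turned to -0.25 without WT replicate 2 and to -0.22 without flu replicate 1.

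The response to flu was set against other splits of the arrays. In a fit of 4 arrays against 4, 1 of the 35 splits, the real one, gave as many calls: 6792 probe sets passed, and the highest of the other splits gave 1. All other splits mix flu arrays with arrays of a functional FLU gene on both sides, so the response itself widens the spread there. Few calls could arise in them, and their low counts do not by themselves exclude chance.

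The poly-A spike-in controls, added to the RNA before labelling, were brighter on the flu tAPX arrays than the mean of the 6 other arrays, by log2 0.72 for replicate 1 and 0.38 for replicate 2. The hybridisation controls, added later, were brighter by 0.34 and 0.47 against the same mean. The excess of the poly-A over the hybridisation controls was 0.38 for replicate 1 and -0.0888 for replicate 2, so array brightness could account for replicate 2 but does not cover replicate 1, and the test decided nothing. A lower amount of messenger RNA per sample would look alike and was not tested. This is the scaling under which all tested genes in flu tAPX against flu shift by a median of -0.51.

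With the pseudocount of 16 added, no tested probe set lay at least 4-fold apart from all other arrays on both WT arrays, and the count was likewise 0 for tAPX. On the signals as deposited the counts were 5 for WT, AT5G24240 among them, and 4 for tAPX, so the 0 depends on the pseudocount.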
